A study of Homo sapiens with 53 samples.

How the data were processed

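Peripheral blood mononuclear cells of 53 separately labelled subjects were profiled on Illumina HT-12 v4 arrays, 1 array per subject: 24 healthy controls, 21 subjects with major depressive disorder (MDD) and 8 with bipolar disorder (BD). Per the labels, the cells were isolated over a density gradient and stored frozen, and globin transcripts were reduced before total RNA was labelled. Groups were taken from the disease label of each sample, and each array was treated as an independent replicate. No pairs of samples are labelled, so no paired test was used. The labels give no sequencing or array batch, cell count, treatment, age, sex or body mass, and none of these was modelled.

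The values deposited by the authors are log2 signals of 43116 probes, with a lowest value of 6.45, a median of 7.09 and a highest value of 14.70 in the deposited values. After sorting, the 53 columns differ by at most 0.0022 at any rank, which is how quantile-normalized arrays look. The background correction, the software and any filter applied before deposit are not given in the sources used here. A second deposited table holds signals and detection p-values before normalization in 106 columns, but its columns carry only running numbers that no label ties to a sample. It was not used here, and the normalized log2 table served as the source of all values. The plan had been to start from that table with background correction by limma's neqc and a filter on detection p-values. In its place a probe was kept when it exceeded the 75th percentile of the array, a floor of 7.49 log2 units, on at least 8 arrays, the size of the smallest group. This replacement was set before any test was run.

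Gene names came from the annotation supplied for the probes of this platform: 27412 probes had 1 name, 7 had several and 15697 had none, and 27374 were matched to a RefSeq gene by gene ID. Probes of XIST and of Y-linked genes (122) were left out, since sex is not a label. The filter left 12337 probes, 9815 of them with 1 name, for 7843 genes. Differences are given on the log2 scale with their standard error, and array numbers limit their precision.

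Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment over all probes tested and a call at an adjusted p under 0.05. Patients of both diagnoses against controls used a fit of 2 groups. MDD against controls, BD against controls and MDD against BD used 1 fit of the 3 groups with a shared estimate of the spread, and BD1-titled against BD2-titled samples a fit of 4 groups. The comparisons, tests, gene lists and naming rule were fixed before the data were examined.

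The naming rule took, in each of the 4 comparisons, up to 10 higher and 10 lower genes past the threshold, filled to 5 in each direction by the smallest unadjusted p where fewer passed and then described as not passing. Of each fixed list it took up to 3 measured members with the smallest p in patients against controls. The same members, where named in the MDD and BD comparisons, keep their place, and the 5 list members named in MDD against BD were chosen after their values were seen because they passed adjusted over the list alone. A gene in a list was represented by its probe with the highest mean signal.

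Of the 21 fixed lists, 9 were cell type markers (T cells, NK and cytotoxic lymphocytes, B cells, plasma cells, monocytes, dendritic cells, neutrophils, platelets and red cell precursors). The others were immediate early genes, NF-kappaB and inflammatory cytokines, type I interferon response, glucocorticoid receptor targets, ribosomal proteins, oxidative phosphorylation, monoamine, neurotrophin and stress hormone signalling, tryptophan-kynurenine pathway, circadian clock, proliferation, T cell activation and regulatory T cells, and heat shock and unfolded protein response. A list score is the mean log2 signal of the measured members on an array. Group means of the 18 lists with at least 5 measured members were compared by two-sided permutation tests. These used 100000 resamples, or all 10518300 relabellings for BD against controls and all 4292145 for MDD against BD, with Benjamini-Hochberg adjustment over the lists within a comparison. Under the alternatives every comparison used 100000 resamples, or 10000 where an array was left out. Limma's camera, with a preset correlation of 0.01 and with an estimated correlation, and its directional fry were run beside them. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 ran the permutations and matplotlib 3.10.9 drew the plots. Files were read in R with the package data.table (version 1.17.8).

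The alternatives tried were no filter, a threshold of 0.10, a fold minimum of 1.2, quality weights for arrays, 5 cell type scores as covariates (T cells, NK cells, B cells, monocytes and platelets), the first principal component as covariate, equal weight of the 2 diagnoses, all probes of a gene in list scores, and leaving out each array in turn. A filter on at least 27 arrays, centring on the median of the tested probes, leaving out arrays whose median correlation with the others lay more than 3 median absolute deviations below the median, the side of the largest gap in the first principal component as a block, and the larger side of that gap alone were added after the data were seen. Agreement of the MDD and BD differences was set beside simulated unchanged groups and beside 100 divisions of the controls into sets of 12, and their overlap was counted in 100 further sets of simulated unchanged groups. Group mean differences of the named genes and list scores were computed again without each array in turn, and those that moved by over 1.5 times are given beside the difference where it was over 0.10 log2 units in size. Values with cell type scores as covariates are not given for genes that belong to 1 of those scores, because such a covariate shrinks its own members. A further pair of gene groups, small nucleolar RNAs with their host genes and zinc finger genes named ZNF, were defined after the probe results were seen and are reported in the closing part.

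The steps were tested on simulated data with the noise of these arrays, 10 sets of 12337 probes with 200 changed probes each. At a change of 0.25 log2 units, 69.7% of changed probes were recovered for pooled patients against controls, 64.0% for MDD, 34.3% for BD and 30.4% for MDD against BD. At 0.5 units these shares were 95.1%, 93.9%, 84.3% and 84.3%. False calls made up 3.4%, 2.67%, 4.81% and 3.53% of the calls. Each simulated set mixed changes of 0.25, 0.5 and 1 log2 units, and many true changes loosen the adjusted threshold. The shares therefore do not give the power in the real data, where few probes were called. There SNHG1 differed by 0.46 in pooled patients and did not pass. For the list test, 5.0% of 900 unchanged tests for pooled patients and 6.11% for MDD had an unadjusted p under 0.05, against 73.9% and 67.9% with a shift of 0.2 units. These shares pool lists of unlike spread, with standard errors in pooled patients from 0.018 (monoamine, neurotrophin and stress hormone signalling) to 0.25 (red cell precursors). They overstate the power for lists with a wide spread. The list test was not simulated for the comparisons with BD.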

Results

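Gene expression was measured on Illumina HT-12 v4 arrays in peripheral blood mononuclear cells, the lymphocytes and monocytes left after density centrifugation of blood. The cells came from 24 healthy controls, 21 subjects with major depressive disorder (MDD) and 8 subjects with bipolar disorder (BD), with 1 array per subject. The number of arrays limits the precision, since the files used here give no bead count or detection value per sample. Of the 43116 probes, 12337 passed the filter on dim signal, and 9815 of these carried 1 gene name. Correlations between any pair of arrays ran from 0.944 to 0.991.

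The arrays fell into 2 sets along the first principal component, which held 28.5% of the variance against 13.7% for the second. A gap of 9.41 units parted 16 arrays on the high side from 37 on the low side. The high side held 10 of 24 controls, 5 of 21 MDD arrays and 1 of 8 BD arrays. These shares did not differ past the threshold between patients and controls (Fisher's exact test, two-sided, p = 0.136, adjusted p = 0.419 over 4 comparisons). Among the controls alone, the score of immediate early genes, which cells transcribe within minutes of a stimulus, was 10.73 ± 0.336 (SD, n = 14) on the low side and 10.05 ± 0.311 (SD, n = 10) on the high side. In the same controls the score of NF-kappaB and inflammatory cytokine genes was 0.48 log2 units higher on the low side, that of oxidative phosphorylation 0.29 higher and that of plasma cells 0.43 higher. The labels give no batch or cell count to set beside this split.

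**Figure D1:**
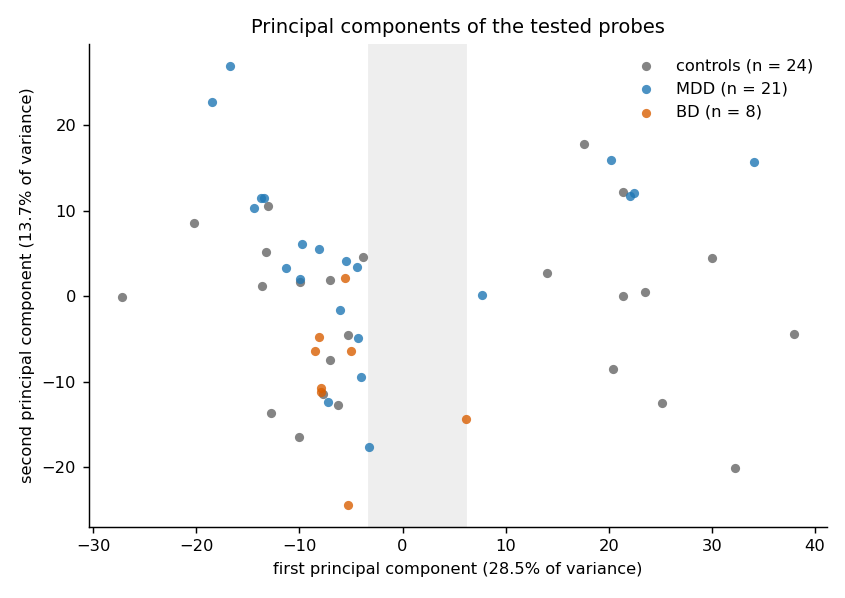
Each point is 1 array, placed by its first principal component (28.5% of the variance) and its second (13.7%), in component units, coloured by group. The shaded band is the empty stretch of 9.41 units, with 16 arrays to its right, 10 of them from controls.

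The series asks how gene expression in blood cells of patients with mood disorders differs from that of healthy controls. With both diagnoses pooled, SNORD12C (probe ILMN_3249286) was higher in patients by 0.34 ± 0.065 log2 units (SE, n = 29 and 24), a fold of 1.26, and was the 1 probe of 12337 past the threshold. SNORD12C is a C/D box small nucleolar RNA, of the class that guides methylation of ribosomal RNA. Whether this probe and those of other small nucleolar RNAs read the small RNA or a longer transcript with its sequence was not tested. The mean SNORD12C signal was 8.26 ± 0.249 in patients and 7.92 ± 0.229 in controls (SD), and 24 of 29 patients lay above the control median (limma, adjusted p = 0.0342). The named genes that came next among those with more signal in patients were also small nucleolar RNAs or genes that host them, none past the threshold. SNORA24, of the class that guides pseudouridylation, differed by 0.18 ± 0.037 (adjusted p = 0.0557, 28 of 29 patients above the control median), and SNHG1, a host gene of several such RNAs, by 0.46 ± 0.11 (adjusted p = 0.153, 28 of 29).

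Below these ranked SNHG7 at 0.21 and SNORA61 at 0.29 log2 units, both with an adjusted p of 0.255 and higher in 23 of 29 patients. A further SNHG7 probe gave the opposite sign at -0.23, and the ranked SNHG7 probe was below the signal floor on 38 arrays. The 5 lowest-p genes with less signal in patients did not pass either, with adjusted p from 0.153 to 0.342. They were SLCO3A1, an organic anion transporter, at -0.25 ± 0.056, KMT2C, a histone methyltransferase, at -0.17 ± 0.041, CTSZ, a lysosomal cathepsin, at -0.38 ± 0.098, CSTA, a protease inhibitor, at -0.26 ± 0.069, and RPS6KA3, a growth factor-responsive kinase, at -0.25 ± 0.068. The KMT2C probes did not all share a sign, with 1 of 3 others at 0.042. On the larger side of the gap alone KMT2C was at -0.084 and CSTA at -0.17. At an unadjusted p under 0.05 there were 960 probes, 482 higher and 478 lower, where the mean expected by chance is 617. Probes are correlated, so such counts can stray far from that mean by chance. Here and in the comparisons below the distance from 617 was not tested. The SNORD12C call ended, with 0 probes called, in 4 alternatives that changed its difference little. It was 0.34 without the filter on dim probes (adjusted p = 0.0637), 0.30 with 5 cell type scores as covariates (adjusted p = 0.300), 0.31 with the first principal component (adjusted p = 0.122) and 0.30 with the side of the gap as a block (adjusted p = 0.159). Weighting arrays by quality called 8 probes, a stricter filter 2, and the larger side of the gap alone 3.

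The count for pooled patients rested on single arrays. It was 0 without any 1 of control replicates 1, 2, 6, 7, 16, 17, 18, 20, 21 and 24, MDD replicates 6, 8, 9, 12, 14, 17, 19 and 20, and BD replicates 1, 5 and 6. It was 2 without control replicates 3, 5, 9, 22 or 23, MDD replicates 10, 11 or 15, or BD replicates 2, 4, 7 or 8, 3 without MDD replicate 2 and 4 without control replicate 11. Across these runs the SNORD12C difference stayed between 0.32 and 0.36.

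**Figure D2:**
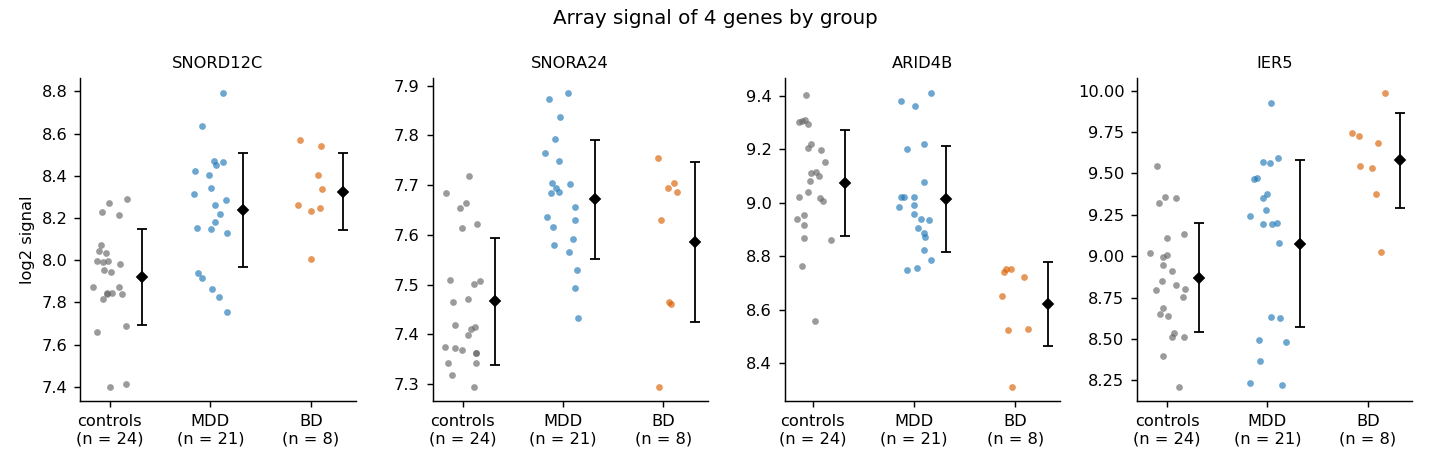
Log2 signal of SNORD12C, SNORA24, ARID4B and IER5 on each array (points) in 24 controls, 21 MDD and 8 BD samples, with the group mean and SD (diamond and bar). SNORD12C has a mean of 7.92 in controls and 8.26 over the 29 patients, and ARID4B a mean of 8.62 in BD and 9.07 in controls.

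Among cell type markers, T cell genes were higher in patients on average. The T cell score differed by 0.098 ± 0.049 log2 units (SE, n = 29 and 24), 12 of 13 measured members had more signal in patients, and 24 of 29 patients lay above the control median (permutation test, two-sided, p = 0.0467, adjusted p = 0.428). CD6, a T cell receptor co-signalling protein, differed by 0.26 ± 0.072, LCK, the kinase that starts T cell receptor signalling, by 0.14 ± 0.067, and CD8A, a co-receptor of cytotoxic T cells, by 0.24 ± 0.12. The 2 further probes of each gene did not share a sign, at 0.101 and -0.0239 for LCK and at -0.0107 and 0.225 for CD8A. CD6 was the 1 T cell gene past the threshold when adjusted over the list alone (adjusted p = 0.00749), and 0 T cell genes passed over all probes. The T cell score also followed the gap between the arrays: among controls alone it was 0.18 higher on the low side, which held 23 of 29 patients and 14 of 24 controls. The patient difference was 0.073 with the first principal component as covariate (permutation p = 0.119), 0.070 with the side of the gap as a block (p = 0.136) and 0.037 on the larger side of the gap alone (p = 0.530). There LCK was at 0.025, CD8A at 0.064 and CD6 at 0.23. Monocyte, dendritic and NK cell genes lay on the other side, with 11 of 12, 5 of 5 and 9 of 11 members lower in patients. The monocyte score differed by -0.085 ± 0.060 (p = 0.175, lower in 17 of 29 patients), with VCAN at -0.19 ± 0.071 and the lipopolysaccharide co-receptor CD14 at -0.18 ± 0.076. The dendritic cell score differed by -0.11 ± 0.056 (p = 0.0602, lower in 22 of 29), with CD1C, a lipid antigen-presenting molecule, at -0.14 ± 0.084. The NK and cytotoxic score differed by -0.11 ± 0.12 (p = 0.340), or by -0.073 without MDD replicate 2 and -0.069 without control replicate 9, with the receptor genes KLRF1 at -0.29 ± 0.15 and KLRD1 at -0.20 ± 0.13 and the adaptor SH2D1B at -0.30 ± 0.11. CD14 was at -0.067 and the dendritic cell score at -0.065 on the larger side of the gap, and the NK score at -0.17 with the first principal component as covariate.

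Scores of the other blood cells did not pass either. Red cell precursor genes were 0.38 ± 0.25 higher on average (permutation p = 0.146), with 6 of 6 members on that side and the haemoglobin genes HBA2 at 0.57 ± 0.33 and HBB at 0.48 ± 0.28, in a series whose RNA had been depleted of globin transcripts. Without BD replicate 6 the red cell difference was 0.25, and with 5 cell type scores as covariates it was 0.24, with HBA2 at 0.34 and HBB at 0.22. Plasma cell genes were 0.16 ± 0.097 higher (p = 0.119), with IGLL1 at 0.42 ± 0.18 and TXNDC5 at 0.18 ± 0.097. The plasma cell score followed the gap, being 0.43 higher on its low side among controls alone, and on that side the patient difference was 0.024, with IGLL1 at 0.075 and TXNDC5 at 0.0059. The B cell score differed by -0.033 ± 0.080 (p = 0.687), with CD22 at -0.050 ± 0.041 and below the signal floor on 43 of 53 arrays, which makes that value uncertain, and the platelet score by -0.0095 ± 0.094 (p = 0.921), with GP1BA at -0.082 ± 0.046. On the larger side of the gap alone the B cell score had the opposite sign at 0.013, as had the platelet score at 0.072 and the dendritic cell gene CD1C at 0.046. For neutrophils, proliferation, and T cell activation with regulatory T cells, 3, 2 and 4 members were measured, which was too few for a test, and the scores differed by 0.024 ± 0.047, 0.055 ± 0.10 and 0.019 ± 0.041. Their top members were MMP25 at 0.14 ± 0.081, PCNA at 0.17 ± 0.099, or 0.043 on the larger side, and CTLA4 at 0.18 ± 0.093, or 0.073 with 5 cell type scores as covariates.

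Genes of cell activation were higher in patients on average without passing. The immediate early score differed by 0.23 ± 0.13 log2 units (permutation p = 0.0921, adjusted p = 0.428, 20 of 29 patients above the control median), with 16 of 17 members on that side. CD69, an early activation marker of lymphocytes, was at 0.44 ± 0.17, RGS1, a regulator of G protein signalling, at 0.49 ± 0.20, and the stress-induced transcription factor ATF3 at 0.19 ± 0.082. The NF-kappaB and inflammatory cytokine score differed by 0.20 ± 0.12 (p = 0.0986, adjusted p = 0.428, 20 of 29), with IL1B at 0.34 ± 0.22 and TNFAIP3, an inhibitor of NF-kappaB, at 0.28 ± 0.18. TNF, an inflammatory cytokine, differed by 0.46 ± 0.13 and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.00804), with 0 members past it over all probes. On the low side of the gap, where both scores ran higher among controls, the patient difference was 0.083 for immediate early genes (permutation p = 0.534) and 0.12 for NF-kappaB genes (permutation p = 0.410). IL1B was at 0.20 and TNFAIP3 at 0.12 there, and with the side of the gap as a block CD69 was at 0.24, RGS1 at 0.29 and ATF3 at 0.12. ATF3 was below the floor on 21 arrays.

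The other process lists had smaller differences. Heat shock and unfolded protein response genes differed by 0.042 ± 0.033 (permutation p = 0.193), with HSPH1 at 0.19 ± 0.081 and ATF4 at 0.14 ± 0.074. Glucocorticoid receptor targets differed by 0.050 ± 0.071 (p = 0.487), with DDIT4 at 0.27 ± 0.17 and CXCR4 at 0.22 ± 0.15. Monoamine, neurotrophin and stress hormone genes differed by 0.018 ± 0.018 (p = 0.334), with the mineralocorticoid receptor gene NR3C2 at 0.11 ± 0.059. Circadian clock genes differed by -0.020 ± 0.023 (p = 0.385), with CSNK1E at -0.23 ± 0.13. Ribosomal protein genes differed by -0.0098 ± 0.025 (p = 0.697), with RPL5 at -0.14 ± 0.080, and the score by -0.040 with 5 cell type scores as covariates (p = 0.0300, adjusted p = 0.203). Type I interferon response genes differed by -0.028 ± 0.11 (p = 0.798, MX1 at -0.21 ± 0.17), tryptophan-kynurenine genes by -0.028 ± 0.049 (p = 0.562, AFMID at -0.38 ± 0.28) and oxidative phosphorylation genes by 0.022 ± 0.051 (p = 0.660, COX4I1 at -0.18 ± 0.092). With the first principal component as covariate these last 3 scores had the opposite sign, at 0.0063, 0.0055 and -0.029, as had MX1 at 0.014, AFMID at 0.20 and the circadian clock score at 0.0025 on the larger side of the gap alone. The median member of the tryptophan-kynurenine list, at 0.045, had the opposite sign to its score. On the larger side HSPH1 was at 0.077, DDIT4 at 0.16, CSNK1E at -0.038, RPL5 at -0.0073 and COX4I1 at -0.018, and with 5 cell type scores as covariates CXCR4 was at 0.12 and NR3C2 at 0.013, while weighting arrays by quality put CXCR4 at 0.33 (p = 0.0259). ATF4 was at 0.080 with the side of the gap as a block. In these lists 0 members passed the threshold over all probes and 0 adjusted over the list alone.

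In pooled patients 0 of 18 lists passed by the permutation test after adjustment, and the T cell list alone had an unadjusted p under 0.05. Camera with a preset correlation called 8 lists, and camera with an estimated correlation and fry called 0. For T cells, monocytes, dendritic cells, immediate early genes and NF-kappaB genes, the adjusted p = 0.586 with an estimated correlation. For plasma cells and red cell precursors the adjusted p = 0.610 with an estimated correlation, and for NK cells the adjusted p = 0.653 with an estimated correlation.

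In MDD against healthy controls, which asks about the first of the 2 diagnoses alone, SNORA24 (probe ILMN_3248890) was higher by 0.21 ± 0.040 log2 units (SE, n = 21 and 24), a fold of 1.15. It was the 1 probe past the threshold, and 21 of 21 MDD samples lay above the control median (limma, adjusted p = 0.0437). Its signal was low, 7.67 ± 0.120 in MDD and 7.47 ± 0.128 in controls (SD), and below the floor of 7.49 on 19 of 53 arrays. SNORD12C at 0.32 ± 0.071 (adjusted p = 0.156, 16 of 21 above the control median) and SNORA61 at 0.30 ± 0.077 (adjusted p = 0.382, 17 of 21) followed without passing. FAM229B at 0.34 and SPINT3 at 0.15 completed the higher genes, the latter below the floor on 44 arrays.

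The 5 genes that ranked first among those lower in MDD did not pass. They were the carbonyl reductase DHRS4 at -0.24 ± 0.055 (adjusted p = 0.156, 18 of 21 below the control median), SLCO3A1 at -0.23, the 14-3-3 protein gene YWHAB at -0.19, CTSZ at -0.40 and RAB5IF at -0.22, the last 4 with an adjusted p of 0.382. RAB5IF was at -0.12 with 5 cell type scores as covariates. At an unadjusted p under 0.05 there were 1189 probes, 676 higher and 513 lower, against a chance mean of 617 without a tested spread. In MDD the T cell score was 0.11 ± 0.052 higher (permutation p = 0.0391, adjusted p = 0.465, 18 of 21 above the control median), 0.090 with the first principal component as covariate (p = 0.0755) and 0.045 on the larger side of the gap alone (p = 0.50). CD6 at 0.29 ± 0.078 passed adjusted over the list alone (adjusted p = 0.00716) with 0 members past the threshold over all probes, and LCK was at 0.16 ± 0.073, and at 0.059 on the larger side. The monocyte score differed by -0.13 ± 0.069 (p = 0.0516, adjusted p = 0.465, lower in 14 of 21), with 12 of 12 members lower. CD14 at -0.23 ± 0.081, VCAN at -0.21 ± 0.078 and FCN1, a lectin of monocytes, at -0.21 ± 0.083 had the smallest p, and 0 monocyte genes passed adjusted over the list alone or over all probes. On the larger side of the gap CD14 was at -0.12. The dendritic cell score differed by -0.10 ± 0.057 (p = 0.0887), the immediate early score by 0.15 ± 0.15 (p = 0.310) and the NF-kappaB score by 0.14 ± 0.14 (p = 0.308), or 0.081 without MDD replicate 12. With the side of the gap as a block the immediate early difference was 0.030 and the NF-kappaB difference 0.047. With 5 cell type scores as covariates the immediate early difference was 0.24 (p = 0.0911) and the dendritic cell difference -0.043. By the permutation test 0 of 18 lists passed after adjustment, the T cell list alone had an unadjusted p under 0.05, and camera with an estimated correlation and fry called 0. Camera with a preset correlation called T cells, monocytes and immediate early genes. The adjusted p = 0.719 with an estimated correlation for T cells and for monocytes, and the adjusted p = 0.843 with an estimated correlation for immediate early genes.

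The SNORA24 call in MDD ended, with 0 probes called, under a fold minimum of 1.2, which its fold of 1.15 does not reach. It also ended in 6 alternatives that changed its difference little. The difference was 0.21 without the filter (adjusted p = 0.155), 0.18 with cell type scores (adjusted p = 0.393), 0.20 with the first principal component (adjusted p = 0.0886), 0.20 with the side of the gap as a block (adjusted p = 0.0988), 0.20 without the 2 poorly correlated arrays (adjusted p = 0.102) and 0.21 on the larger side of the gap alone (adjusted p = 0.201). Weighting arrays by quality called 4 probes. The count in MDD was also 0 without any 1 of control replicates 1, 2, 4, 6, 7, 8, 10, 12, 13, 14, 15, 16, 17, 18, 19, 20, 21 and 24 or MDD replicates 1, 2, 4, 5, 6, 7, 8, 9, 12, 13, 14, 17, 20 and 21, and was 3 without MDD replicate 18.

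In BD against healthy controls, which asks about the other diagnosis, ARID4B (probe ILMN_2269564) was lower by 0.45 log2 units, with a mean of 8.62 ± 0.158 in BD (SD, n = 8) and 9.07 ± 0.198 in controls (SD, n = 24). ARID4B encodes a subunit of the Sin3 histone deacetylase complex, a repressor of transcription. It was the 1 probe past the threshold (difference -0.45 ± 0.081, limma, adjusted p = 0.00911), and 8 of 8 BD samples lay below the control median. The other 2 ARID4B probes had the same sign, at -0.11 and -0.28. None of the genes next in rank passed. Those with more signal in BD included IER5, an immediate early gene, at 0.71 ± 0.16 (limma, adjusted p = 0.111, 8 of 8 above the control median), the tubulin gene TUBB4B at 0.52 ± 0.12, SNORD12C at 0.40 ± 0.097 and SOCS1, an inhibitor of cytokine signalling, at 0.38 ± 0.093. The SOCS1 size is uncertain, since its control mean of 7.42 lay under the floor of 7.49 and 24 of 53 arrays were below it. Those with less signal included KMT2C at -0.26 ± 0.058, where 1 of 3 other probes differed in sign, the splicing factor RBM39 at -0.49 ± 0.11, ZYG11B, a receptor of a ubiquitin ligase, at -0.36 ± 0.085, and ERGIC2, a protein of early secretory membranes, at -0.32 ± 0.076. On the larger side of the gap KMT2C was at -0.14 and ERGIC2 at -0.21, and the mean of KMT2C in BD (7.47) was under the floor. At an unadjusted p under 0.05 there were 1434 probes, 715 higher and 719 lower, against a chance mean of 617 without a tested spread.

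Activation genes were higher in BD than in controls on average. The immediate early score differed by 0.42 ± 0.14 log2 units (SE, n = 8 and 24), with 17 of 17 measured members and 8 of 8 BD samples on the higher side (exact permutation test, two-sided, p = 0.0250, adjusted p = 0.225). RGS1 was at 0.76 ± 0.29, CD69 at 0.38 ± 0.26 and ATF3 at 0.33 ± 0.12, and 0 members passed adjusted over the list alone or over all probes. The NF-kappaB and inflammatory cytokine score differed by 0.38 ± 0.16 (exact p = 0.0225, adjusted p = 0.225, 8 of 8 BD samples above the control median), with 8 of 9 members higher. The highest BD value of this score, 9.97, stood apart from the next, 9.26, and raises the BD mean. TNF at 0.79 ± 0.19 passed adjusted over the list alone (adjusted p = 0.000807 by limma) and not over all probes (limma, adjusted p = 0.111), and IL1B at 0.56 ± 0.32 and TNFAIP3 at 0.37 ± 0.26 did not pass. Without BD replicate 1 IL1B was at 0.30, TNFAIP3 at 0.17 and CD69 at 0.24, while CD69 was at 0.63 without BD replicate 4 and TNFAIP3 at 0.22 without BD replicate 3. On the low side of the gap, which held 7 of 8 BD arrays, the immediate early difference was 0.20 (permutation p = 0.189 by resampling). The NF-kappaB difference there was 0.23 (permutation p = 0.170 by resampling). IL1B was at 0.20 there, and with the side of the gap as a block RGS1 was at 0.47, CD69 at 0.11 and TNFAIP3 at 0.17.

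Of the cell type markers, 8 of 8 B cell genes had less signal in BD, and the B cell score differed by -0.21 ± 0.13 (exact p = 0.0910, adjusted p = 0.409, lower in 5 of 8 BD samples), or by -0.13 without BD replicate 8. Red cell precursor genes were 0.62 ± 0.54 higher (exact p = 0.154), a difference carried by BD replicate 6, without which it was 0.12. Circadian clock genes differed by -0.069 ± 0.031 (exact p = 0.0588, adjusted p = 0.353, lower in 5 of 8), or by -0.023 on the larger side of the gap. By the exact permutation test 0 of 18 lists passed after adjustment in BD, the immediate early and NF-kappaB lists had an unadjusted p under 0.05, and camera with an estimated correlation and fry called 0. Camera with a preset correlation called immediate early genes, NF-kappaB genes, B cells and dendritic cells, for which the adjusted p = 0.396 with an estimated correlation. It also called red cell precursors, for which the adjusted p = 0.502 with an estimated correlation, and oxidative phosphorylation genes, for which the adjusted p = 0.711 with an estimated correlation.

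The ARID4B call in BD ended, with 0 probes called, without the filter on dim probes, where the difference stayed at -0.45 (limma, adjusted p = 0.0683), and on the larger side of the gap alone, where it was -0.38 (limma, adjusted p = 0.141). Weighting arrays by quality called 8 probes, and the cell type scores or the first principal component as covariates called 2 each, ARID4B among them in each. The count in BD was 0 without BD replicate 1, 2 or 3 and 9 without BD replicate 4, and the ARID4B difference stayed between -0.47 and -0.41 without each array in turn.

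**Figure D3:**
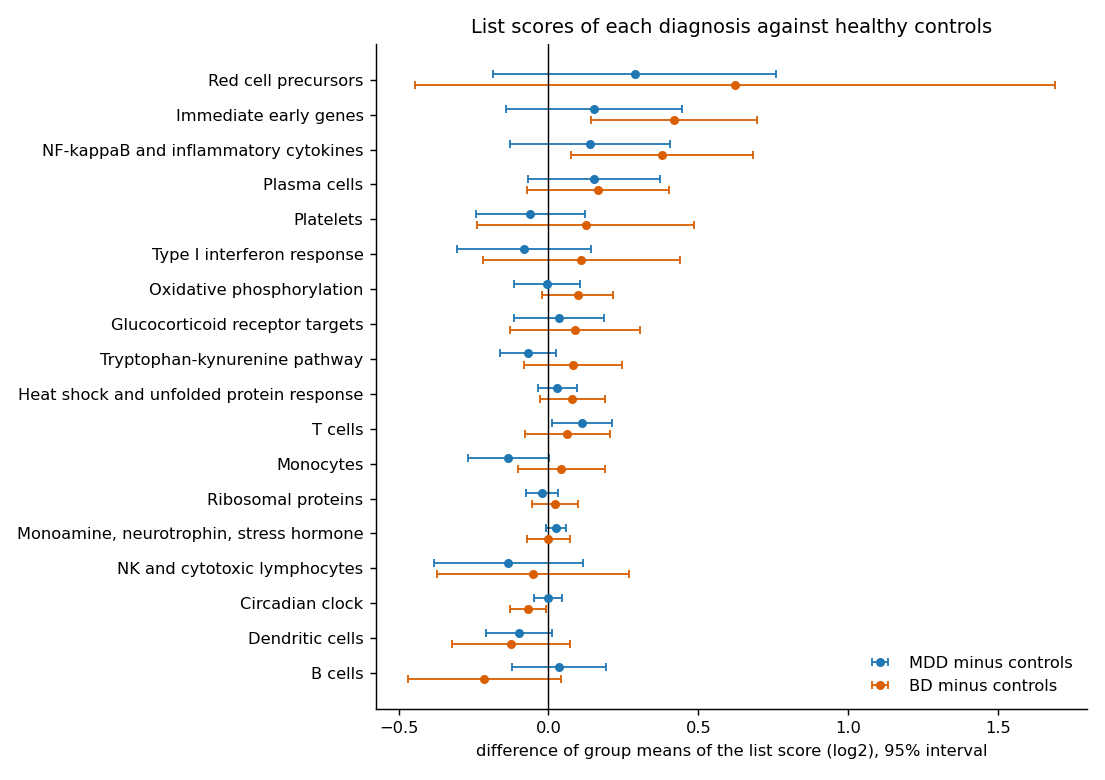
Difference of the group means of each of 18 list scores, MDD minus controls and BD minus controls, in log2 units, with its 95% interval. The immediate early score differs by 0.42 in BD and 0.15 in MDD, and the T cell score by 0.063 in BD and 0.11 in MDD.

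**Figure D4:**
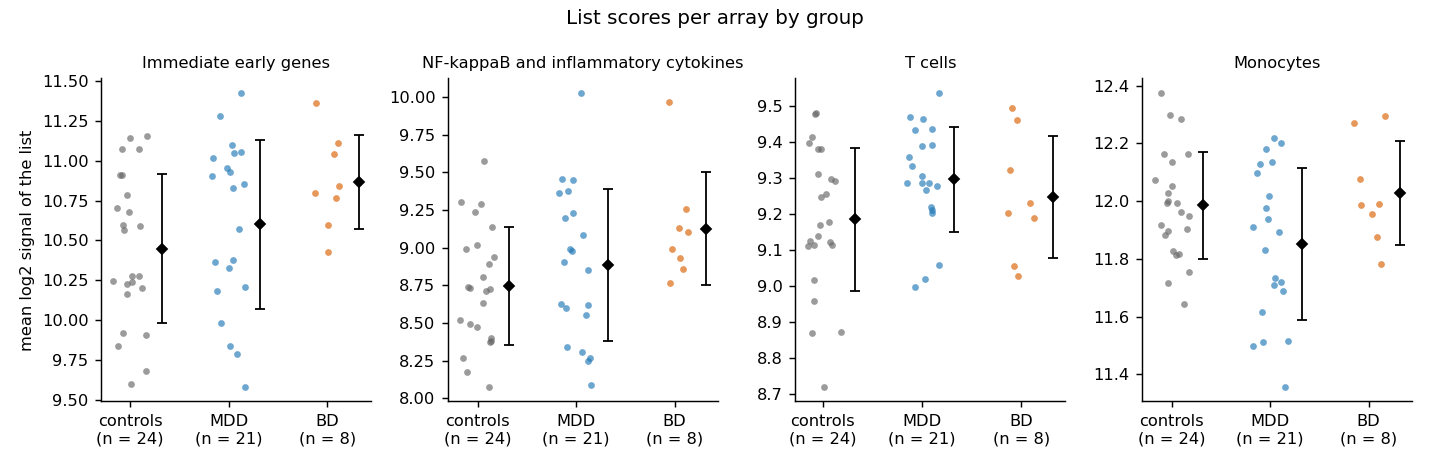
List scores of each array (mean log2 signal of the measured members) for immediate early genes, NF-kappaB and inflammatory cytokine genes, T cell genes and monocyte genes, with the group mean and SD, in 24 controls, 21 MDD and 8 BD samples. The 8 BD arrays have a mean immediate early score of 10.87 against 10.45 in controls.

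MDD was then set against BD, which tests whether the 2 diagnoses differ from each other. The genes first in rank were ARID4B, higher in MDD by 0.39 ± 0.082 log2 units (SE, n = 21 and 8, limma, adjusted p = 0.0824, 21 of 21 MDD samples above the BD median), and the zinc finger genes ZNF773 at 0.75 ± 0.18 and ZNF493 at 0.40 ± 0.096. With them stood the pseudogene SNX29P2 at 0.80 ± 0.18 and HSCB, a co-chaperone of iron-sulfur cluster assembly, at 0.68 ± 0.17, although a further HSCB probe was at -0.089. Lower in MDD were the antioxidant enzyme gene GPX1 at -0.58 ± 0.14, CREG1, a protein of lysosomes, at -0.54 ± 0.13, SASH1 at -0.39 ± 0.094, the endocytic gene EHD4 at -0.31 ± 0.071 and DPM2, of dolichol-phosphate mannose synthesis, at -0.26 ± 0.066. DPM2 was at -0.15 without BD replicate 6. DPM2 and ZNF493 were below the floor on 15 arrays each, and the ZNF493 mean in BD (7.41) lay under it. None of these passed. The limma fit called 0 probes, with 2 at an adjusted p under 0.10. At an unadjusted p under 0.05 there were 1808 (920 higher and 888 lower), against a chance mean of 617 without a tested spread.

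Among the lists in MDD against BD, 8 of 8 B cell genes were higher in MDD and the B cell score differed by 0.25 ± 0.13 (exact permutation p = 0.0341, adjusted p = 0.205, 19 of 21 MDD samples above the BD median). MS4A1, which encodes CD20, was at 0.38 ± 0.13 and passed adjusted over the list alone (adjusted p = 0.0375 by limma), with a difference of 0.24 when arrays were weighted by quality. The circadian clock score was 0.067 ± 0.029 higher (exact p = 0.0254, adjusted p = 0.205, 20 of 21), or 0.036 on the larger side of the gap, and the tryptophan-kynurenine score differed by -0.15 ± 0.080 (exact p = 0.0297, adjusted p = 0.205, lower in 17 of 21), or by -0.078 with 5 cell type scores as covariates. WARS1, an interferon-inducible tryptophan tRNA synthetase, was at -0.50 ± 0.16 and passed adjusted over the list alone (adjusted p = 0.0254 by limma), with a difference of -0.30 without BD replicate 8 and -0.29 with 5 cell type scores. The transcription factor gene CREB1 at 0.31 ± 0.10, the class II antigen-presentation gene HLA-DRA at -0.33 ± 0.10 and LCN2, a protein of neutrophil granules, at -0.38 ± 0.15 also passed adjusted over the list alone, with adjusted p of 0.0241, 0.00576 and 0.0347 by limma. Their lists are those of monoamine and stress hormone genes, T cell activation (4 measured members) and neutrophils (3), and the 5 members given here were named after their values were seen. Over all probes 0 list members passed. The monocyte score differed by -0.18 ± 0.085 (exact p = 0.0900, lower in 14 of 21), with 12 of 12 members lower in MDD, or by -0.11 on the larger side of the gap. The immediate early score differed by -0.27 ± 0.16 (exact p = 0.191) and the NF-kappaB score by -0.24 ± 0.17 (exact p = 0.230), or -0.12 without BD replicate 1, so the difference between the 2 diagnoses in these scores did not pass. With 5 cell type scores these were -0.14 and -0.16.

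In MDD against BD 0 of 18 lists passed by the exact permutation test after adjustment, the circadian clock, tryptophan-kynurenine and B cell lists had an unadjusted p under 0.05, and camera with an estimated correlation and fry called 0. Camera with a preset correlation called B cells, monocytes, platelets, immediate early genes, type I interferon response and oxidative phosphorylation, and for each of these 6 the adjusted p = 0.635 with an estimated correlation. With the first principal component as covariate limma called 87 probes, 67 higher and 20 lower in MDD. Among them were ARID4B at 0.37 (adjusted p = 0.0290), ZNF773 at 0.79 and GPX1 at -0.59. Weighting arrays called 1 probe and the side of the gap as a block 2, and 9 probes were called without MDD replicate 10 and 1 without MDD replicate 2 or BD replicate 5.

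Titles divide the BD samples into 4 that start with BD1 and 4 that start with BD2, and the labels do not say what the digit stands for. Between them limma called 0 probes, with 393 at an unadjusted p under 0.05 where the chance mean is 617, and 0 without each BD array in turn.

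Across the 12337 probes, the log2 differences of MDD and of BD from controls had a correlation of r = 0.153, with a jackknife error over arrays of 0.355. Probes are not independent replicates, and both differences share the 24 controls. Unchanged simulated groups set against shared controls gave a mean r of 0.326 (95% of draws between -0.221 and 0.723), so the observed value did not exceed what the shared controls give. With the controls divided into separate sets of 12 for each diagnosis, 100 draws gave a mean r of -0.0060. At an unadjusted p under 0.05, 71 probes were higher in both diagnoses and 77 lower in both. Unchanged simulated groups with shared controls gave a mean of 30.2 higher in both (95% of draws between 3.48 and 128, at least as many as observed in 9 of 100) and 31.0 lower in both (5 to 180, 7 of 100), so the observed overlap lay within what the shared controls give.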

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

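The groups of small nucleolar RNA and ZNF genes, the tests of cell composition, array structure and activation on the small nucleolar RNA pattern, the test of array structure on the BD scores and the counts of splits for the 5 comparisons as reported were chosen after the results were seen.

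The first pattern is that small nucleolar RNAs and their host genes lay together on the higher side in patients. Of 58 probes for 57 genes, 50 were higher, 20 of them at an unadjusted p under 0.05 where 2.41 were expected, and the mean score differed by 0.099 ± 0.037 (SE, n = 29 and 24, permutation p = 0.00815, adjusted p = 0.0317 over 8 tests, 24 of 29 patients above the control median). With the first principal component as covariate the difference was 0.068 (95% interval 0.0066 to 0.129). With the immediate early score, a stand-in for activation during handling, it was 0.062 (0.0016 to 0.123). Both intervals stayed above 0, while the 5 cell type scores left 0.073 with an interval from -0.0042 to 0.150. These adjusted values lie close together. The group was also defined from members seen to be high in these samples, which raises its difference. The intervals therefore cannot decide, and array structure, activation and cell composition each stay open. Diagnosis is a biological difference that stays open as well, as a hypothesis found and tested on the same samples. Age, sex, body mass and medication are not labelled. A difference in age, body mass or medication cannot be told apart from diagnosis. Sex was not checked here, so a difference in sex stays open too.

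The second pattern is the higher mean of the immediate early and NF-kappaB scores in BD, 0.399 ± 0.181 (SE) with both scores averaged. With the 5 cell type scores as covariates it was 0.325 ± 0.176 (95% interval -0.029 to 0.679), and with the first principal component 0.259 ± 0.153 (-0.048 to 0.567). The difference kept 81.3% and 65% of its size, and each interval reached below 0, so neither cell composition nor array structure is excluded. These scores differed by 0.68 and 0.48 between the 2 sides of the gap among controls alone. The component was computed from probes that include these genes, so such a difference is partly built in and does not show its cause. For the same reason that component as covariate can shrink these scores. A difference in how the frozen cells were handled may take part, and no label gives the handling per sample. Diagnosis stays open too, as do age, sex, body mass and medication, which are not labelled.

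The third pattern is the 87 probes called in MDD against BD with the first principal component as covariate, where 0 were called without it. The 2 diagnoses also parted along the second component. Every BD array except replicate 6 (2.10) had a negative value there, down to -24.42 for replicate 8, while most MDD values were positive. The second component was not a covariate in this setting, so whether its unexplained structure takes part in the calls was not tested. All 87 kept their direction without the covariate and 83 had an unadjusted p under 0.05 there. In this setting 1 of 100 splits of the MDD and BD arrays, the real one, gave as many, and the highest of the others gave 8. By that count alone chance would be excluded for the 87. The setting called the most probes of those tried, however, and the count makes no allowance for that choice. The side of the gap as a block, another form of the same structure, called far fewer. Chance is therefore not taken as excluded. With the monocyte score as a second covariate the 87 probes kept a median share of 0.824 of their difference (quartiles 0.799 and 0.870). The probes were picked for their differences without that covariate, and a marker score measures monocyte content imperfectly. The share therefore cannot decide how much monocyte content contributes. The monocyte covariate ended every call (limma, lowest adjusted p = 0.144). The median size of the difference went from 0.51 to 0.41 log2 units while its standard error stayed at 0.118. Monocyte content remains a candidate.

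For pooled patients against controls the real split called 1 probe, as many as in 3 of 100 splits with the real one included and at most 2 in the others. For MDD against controls it was 1 probe, 3 of 100 and at most 1. By these counts chance would be excluded for both, but a count of 1 probe repeats little more than its adjusted p (0.0342 and 0.0437). Each call also ended without single arrays, so neither count is taken to exclude chance. Chance cannot be excluded for BD against controls either, where 6 of 100 splits called at least 1 probe and the highest of the others called 207.

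The count cannot test chance for MDD against BD or for BD1-titled against BD2-titled samples, because the real split called 0 probes and every split, 100 of 100 and 35 of 35, calls at least as many. The highest of the others called 171 and 15. Splits that call 207, 171 or 15 probes against 1 or 0 point to a structure of the samples, which was tested for 2 of them after they were seen. The split with 171 parted the arrays along the first principal component more than any of the others, by 18.1 units against a median of 3.87, and called 0 probes with that component as covariate. The split with 207 parted them by 13 units, with 8 others above it. It still called 149 with that component as covariate and 205 with the second component added. Neither component accounts for it, and its structure is open, as is that of the split with 15.

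In 12 of 93 sets of 8 BD values checked, 1 sample stood apart from the other 7, by a gap to its nearest neighbour divided by the range of all 8. Chance gives this in about 1 in 20 groups. The highest sample stood apart for VCAN (0.818), the red cell precursor score (0.781), CREG1 (0.682), RBM39 (0.677), DPM2 (0.613), HBA1 (0.603), the NF-kappaB score (0.590) and HLA-DRA (0.573). The lowest stood apart for ATF4 (0.626), ZNF493 (0.575), FAM229B (0.542) and the platelet score (0.528).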

How the results depend on the processing

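The alternatives with a stricter filter, centred arrays, poorly correlated arrays left out, or the gap in the first principal component were chosen after the data were seen. Against 1 probe called in each comparison with controls and 0 in MDD against BD, an adjusted p under 0.10 called 2 for pooled patients and 2 for MDD against BD, and a fold of at least 1.2 left 0 for MDD. Without the filter on dim probes, which raises the number tested, 0 were called for patients, 0 for MDD and 0 for BD. With arrays weighted by quality the counts were 8 for patients, 4 for MDD, 8 for BD and 1 for MDD against BD. With 5 cell type scores they were 0, 0 and 2 for patients, MDD and BD. With the first principal component they were 0, 0, 2 and 87 for the 4 comparisons. The stricter filter gave 2 for patients, leaving out 2 poorly correlated arrays 0 for MDD, the side of the gap as a block 0 for patients, 0 for MDD and 2 for MDD against BD, and the larger side alone 3, 0 and 0 for patients, MDD and BD. Camera with a preset correlation of 0.01 called 8, 3, 6 and 6 lists against 0. Without each array in turn the counts ranged from 0 to 4 for patients, 0 to 3 for MDD, 0 to 9 for BD and 0 to 9 for MDD against BD, at 0 throughout for BD1-titled against BD2-titled samples and for lists, and the correlation of MDD and BD differences from 0.0582 to 0.254. SNORD12C in patients, SNORA24 in MDD and ARID4B in BD kept their direction in every alternative run, with adjusted p from 0.000916 to 0.300, 0.000461 to 0.393 and 0.000265 to 0.141. Of 862 values of named genes under alternatives 823 kept their direction and side of the threshold, 12 lost it, 24 gained it and 3 reversed. All 12 losses fell on SNORD12C in patients, SNORA24 in MDD and ARID4B in BD, the named results that had passed. The other named results had not passed and could not lose a call, so the count of 823 is no measure of robustness. Of 292 values of list scores 279 kept direction and side and 13 reversed, none of them past the threshold. These values cover 34 combinations of a list and a comparison, not every list in every comparison. Reversals of the list scores outside these 34 were not counted. As no list had passed, none could lose a call either. Reversed in pooled patients were the tryptophan-kynurenine score with cell type scores (0.0025), and with the first principal component the platelet (0.0080), interferon (0.0063), oxidative phosphorylation (-0.029) and tryptophan-kynurenine (0.0055) scores. On the larger side of the gap the scores of B cells (0.013), platelets (0.072), oxidative phosphorylation (-0.039), tryptophan-kynurenine (0.037) and circadian clock (0.0025) and the genes CD1C (0.046), MX1 (0.014) and AFMID (0.20) reversed. Platelets reversed without the poorly correlated arrays (0.024), and interferon (0.0057) and oxidative phosphorylation (-0.039) with the side of the gap as a block. Apart from the number of probes tested, the cause was not tested. Not run, for want of columns that can be tied to samples, were background correction against none, median scaling, detection p filters, array slide as a block and leaving out arrays with few detected probes. No paired analysis was possible because no pairs are labelled. Signal near background limits probes such as SNORA24 and SNHG7, below the floor on 19 and 38 arrays.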

Other observations

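The ZNF zinc finger genes, a family of transcription regulators, were tested as a group only after their members had been seen among the genes of MDD against BD. That choice raises the difference between MDD and BD, so the p-values below describe the group and are no independent test of it. Over 230 probes for 201 genes their mean score was higher in MDD than in BD by 0.094 ± 0.024 log2 units (SE, n = 21 and 8, exact permutation p = 0.00127, adjusted p = 0.0101 over 8 tests), with 19 of 21 MDD samples above the BD median. At an unadjusted p under 0.05, 41 of these probes were higher in MDD where 15.7 were expected, 2 were lower, and 0 passed over all probes by limma. In the same comparison the B cell score was 0.25 higher in MDD and the monocyte score differed by -0.18. With the monocyte score as covariate the ZNF difference was 0.066 ± 0.024 (95% interval 0.018 to 0.114), and with 5 cell type scores 0.057 ± 0.022 (0.013 to 0.101). Against controls the ZNF score differed by 0.052 ± 0.020 in MDD (permutation p = 0.0119, adjusted p = 0.0317, 16 of 21 above the control median) and by -0.042 ± 0.023 in BD (exact permutation p = 0.115, adjusted p = 0.153, 1 of 8 above the control median). Among the 44 named probes higher in MDD with the first principal component as covariate, 9 were ZNF genes. Of all 9815 named probes tested, 230 were ZNF probes. The counts of 41 and 9 come from the comparison that led to the group, so they only describe it.

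The small nucleolar RNA and host gene score differed from controls by 0.091 ± 0.041 in MDD (permutation p = 0.0326, adjusted p = 0.0522, 17 of 21 above the control median) and by 0.12 ± 0.045 in BD (exact permutation p = 0.0323, adjusted p = 0.0522, 7 of 8), neither past the threshold. Both differences share the 24 controls, so their common sign is not independent evidence. MDD and BD differed from each other by -0.031 ± 0.045 (exact permutation p = 0.554). Many of these probes belong to 1 numbered series of the array. Within that series, 12 of 30 small nucleolar RNA or host gene probes (40.0%) and 24 of 468 other named probes (5.13%) were higher in pooled patients at an unadjusted p under 0.05. These shares only describe the group, which includes the genes whose values led to it, and probes of the same arrays are not independent of each other. Among controls alone the score was 8.22 ± 0.137 (SD, n = 14) on the low side of the gap in the first principal component and 8.05 ± 0.0714 (SD, n = 10) on the high side.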
